A study of Homo sapiens with 12 samples.

How the data were processed

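Gene expression was measured with Human Gene 2.0 ST arrays from Affymetrix in HEK293 cells, an adenovirus-transformed human embryonic kidney line. Cells had been transfected with a synthetic mimic of the microRNA miR-1825 or with a control siRNA, per the labels' protocols. The RNA concentration was 5 nM and RNA was taken 24 h after transfection. There were 6 arrays per group and 12 in all. No label says whether the replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

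The deposited table holds 1 value per array for 53617 transcript clusters, the array's units that each gather the probes of a gene or transcript. The values were made with Affymetrix Expression Console, per the submitters' processing notes. Its version and its background correction, normalization and summarisation settings are not given in the sources used here. The deposited values were read as log2 expression, because they run from 1.62 to 14.4 and the array medians lie between 4.44 and 4.51. The values were used as deposited, without further normalization in the main test. Intensities of single probes were not used here, so background levels could not be set. The number of arrays limits the precision.

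Transcript clusters were named through the platform annotation supplied for the array, and symbols were updated through gene identifiers of the RefSeq annotation of GRCh38.p14. Of the 53617 transcript clusters, 16098 had 1 gene symbol, 0 had several and 37519 were unnamed here. Control probe sets were to be left out where they could be recognised, but no rows were left out. The unnamed clusters may therefore include controls that measure no gene or transcript, and every count over all clusters includes them. All 16098 identifiers matched, and 0 symbols changed. The named clusters cover 14884 genes, of which 11916 are protein-coding, 1398 are long non-coding RNA genes and 1072 are microRNA genes. Of the clusters with a mean at or above the median 42.8% were named, against 17.2% of the rest. Where a gene had several clusters, the one with the highest mean over all 12 arrays was used. Several genes discussed have near-identical relatives (pseudogenes or duplicated copies) whose transcripts can bind the same probes, and these are pointed out where they appear. No genome coordinates are given, because the build behind the array's design is not given in the sources used here.

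Designs, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, all clusters, no block), mimic minus control, with a Benjamini-Hochberg adjusted p threshold of 0.05. Every adjusted p of a gene comes from limma. Tests were two-sided. Of 22 gene lists, 20 had at least 5 named members and were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 20 lists. The alpha and beta tubulins and the mitochondrially encoded mRNAs had too few named members and were not analysed here. The lists tested were tubulin folding cofactors, kinesin, dynein and microtubule-binding genes, ALS-linked genes, microRNA pathway, interferon response, G1/S, G2/M, p53 targets, stress response (unfolded protein and integrated), cholesterol synthesis, heat shock, hypoxia, oxidative phosphorylation, ribosomal proteins, lysosome and autophagy, immediate early genes, housekeeping genes, and markers of fibroblasts, leukocytes and epithelial cancer lines. A few genes stand in more than 1 list. For each array a list score was computed as the mean log2 value of the list's genes minus the mean of all 14884 genes. Scores were compared by an exact permutation test over all 924 assignments of 6 of the 12 arrays, for which the smallest possible p is 0.00216.

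The rule for named genes had several parts. It took up to 12 higher and 12 lower genes by size of change among named genes past the threshold, with a mean over all arrays at or above the median of all clusters and with all 6 mimic arrays beyond the control mean. Symbols starting with LOC, MIR, SNOR, RNU, RNA5S or LINC were left to counts. It also took TBCB, TUBA4A and the miR-1825 host gene POFUT1, and the up to 4 members of each list with the smallest p. The first part named 0 genes in the main test over all clusters. The same rule was therefore also applied to the test of the brightest 25% of clusters alone, a filter fixed in advance, and this use of the rule was chosen after the data were seen. TUBA4A was not analysed here. Results that need transcript sequences (a test of miR-1825 seed sites in 3' UTRs, a ranking of 7-base words, enrichment of sites among lower genes, and 6 genes to be named by their sites) were planned and not analysed here, because no sequences were used.

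The replicate numbers 1 to 6 recur in both groups. Deviations from the group means of same-numbered arrays correlated between -0.11 and 0.08 over the clusters at or above the median, so the numbers were not taken to pair the samples. That check does not exclude other structure along the numbers. On the second principal component, replicates 1 to 3 lay above replicates 4 to 6 within each group. A block of replicates 1 to 3 against 4 to 6 was not fitted by itself. The replicate block among the alternatives, which gives each number its own level, includes that contrast. No 2 arrays were identical, and pairwise correlations over all clusters lay between 0.988 and 0.994.

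Alternatives were a replicate block, centring of arrays on their medians, quantile normalization, a trend and robust prior, array weights, filters on dim clusters (mean at or above the median or the 75th percentile), 1 cluster per named gene, a fold minimum of 1.5, a threshold of 0.01, an estimated correlation, fry, all clusters of a listed gene, and leaving out each array. The pipeline was tested on simulated data made with the real means and residual spreads of the 53617 clusters, with 200 changed clusters. The noise was independent between clusters, and the 200 were drawn only from clusters with a mean at or above the median. The pipeline recovered 27 of 67 changes of 1.25-fold (40.3%), 47 of 67 of 1.5-fold (70.1%) and 59 of 66 of 2-fold (89.4%), with 6 false calls. A simulated list of 25 genes shifted by 0.1 gave a camera p of 1.62e-11 and an unshifted list a p of 0.551. Genes of the simulated lists were independent, whereas the real G2/M list had an estimated inter-gene correlation of 0.066. The simulation therefore does not show how camera behaves for correlated genes.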

Results

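The effect of a miR-1825 mimic on the transcriptome of HEK293 cells was measured on 12 arrays, 6 from cells that received the mimic and 6 from cells that received a control siRNA. The series title ties miR-1825 to amyotrophic lateral sclerosis (ALS), a motor neuron disease, and gives the search for mRNA targets as the purpose. The arrays were close to each other, with a mean pairwise correlation of 0.992 within groups and 0.991 between groups over 53617 transcript clusters. The first principal component of the clusters with a mean at or above the median held 18.7% of the variance. The mimic arrays lay higher on it (exact permutation p = 0.00866), although mimic replicates 4 and 5, at -2.30 and -1.31, fell within the range of the controls.

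No named gene passed the threshold of the limma test in the comparison of mimic with control over the whole array. Only 6 of 53617 transcript clusters did, of which 5 were higher and 1 was lower after the mimic, and all 6 are unnamed here. Cluster 16828520 rose from 9.92 ± 0.05 to 10.25 ± 0.01 (log2 value, mean ± SD, n = 6; limma adjusted p = 0.0226), or 1.26-fold. Cluster 17058000 went from 3.36 ± 0.12 to 4.05 ± 0.16, and the single lower one, cluster 16764016, from 3.93 ± 0.09 to 3.48 ± 0.07. These last 2 lay below every array median, where the background was not known, so no fold is given for them. In each of the 6, all 6 mimic arrays lay beyond the control mean. At an unadjusted p under 0.05 there were 5770 clusters, 10.8% against the 5% of chance, with 2874 higher and 2896 lower. Among the named clusters in that set, 1046 were higher and 681 lower. Changes were small: the median standard error was 0.07 in the clusters at or above the median, and only 5 named clusters there differed by 1.5-fold or more, none of them past the threshold. The count of 6 fell to 0 without any one of control replicates 1, 2 and 3 or mimic replicates 1, 2, 4, 5 and 6, and to 2 without control replicate 4 or mimic replicate 3. With a trend and robust prior it was 39 (28 higher, 11 lower), and among clusters at or above the median it was 13.

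Restricting the test to the brightest 25% of clusters, a step chosen for description after the data were seen, gave 242 calls among 13405 clusters, 191 higher and 51 lower after the mimic. These clusters had a mean log2 value of at least 6.29. The excess of higher calls depended on the scaling: after quantile normalization there were 239 calls, 126 higher and 113 lower. The named calls were 102 genes, 91 higher and 11 lower, and 90 of them are protein-coding. The changes were small, with a median size of 0.23 on the log2 scale over the 242, and 13 of the 242 reached 1.5-fold. By the rule for named genes, ZNF714, a zinc finger protein gene, was the most raised of these, from 6.58 ± 0.11 to 7.03 ± 0.14 (1.37-fold, limma adjusted p = 0.0148 in the brightest 25% of clusters). ANKRD12 (1.32-fold) and NUCKS1, which encodes a nuclear chromatin protein (1.26-fold), followed, together with the antisense gene THAP9-AS1 (1.28-fold). SLF1, a factor of the SMC5/6 DNA repair complex, was 1.26-fold higher. CLK1, a kinase that phosphorylates splicing factors of the SR family, was also 1.26-fold higher. MYO3A, a class III myosin gene, had a log2 fold change of 0.32 and DESI2 of 0.25. A further 4 of the 12 most raised have near-identical copies elsewhere and are uncertain as gene assignments: ARHGAP11B, INTS4P2, RGPD3 and RPL21P28, with log2 fold changes of 0.33, 0.32, 0.32 and 0.29.

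Fewer named genes fell in the brightest 25% of clusters. SCARNA5, a small Cajal body RNA, went from 7.51 ± 0.12 to 7.15 ± 0.16 (log2 fold change -0.36, SE 0.08, limma adjusted p = 0.0428). NMB, which encodes the peptide neuromedin B, went from 6.88 ± 0.11 to 6.58 ± 0.11 (log2 fold change -0.30, SE 0.06, limma adjusted p = 0.0357). WIZ, a zinc finger partner of the G9a and GLP histone methyltransferases, had a log2 fold change of -0.24. Those of BOLA1, the F-box gene FBXL19 and NME3, a nucleoside diphosphate kinase gene, were each -0.21. FAT1, an atypical cadherin gene, and ANKRD52, a regulatory subunit of protein phosphatase 6, each had -0.18. TOMM40, the channel of the mitochondrial outer membrane translocase, went from 11.19 ± 0.03 to 11.03 ± 0.05 (log2 fold change -0.17, SE 0.03, limma adjusted p = 0.0285). CCDC88C had -0.15. In all 22 genes named from the brightest 25% of clusters, each of the 6 mimic arrays lay beyond the control mean, as the rule required. The count of 242 was unstable. It fell to 23 without control replicate 2, to 24 without control replicate 4 or mimic replicate 2, and to 26, 47 and 37 without mimic replicates 1, 3 and 6. Without control replicates 1, 3 and 6 it was 102, 145 and 115. It was also 144 with arrays centred on their medians, 448 with a trend and robust prior and 24 in the brightest 40% of clusters. Of the 22 named genes, 1 was still called without mimic replicate 1 or in the brightest 40% of clusters, 2 without control replicate 2 or mimic replicate 2, 3 without mimic replicate 6, 4 without control replicate 4 or mimic replicate 3, and 10 to 12 without control replicate 1, 3 or 6. The direction of all 242 was the same in each of these fits. This says little, because the 242 had been chosen for their difference on these arrays.

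**Figure D1:**
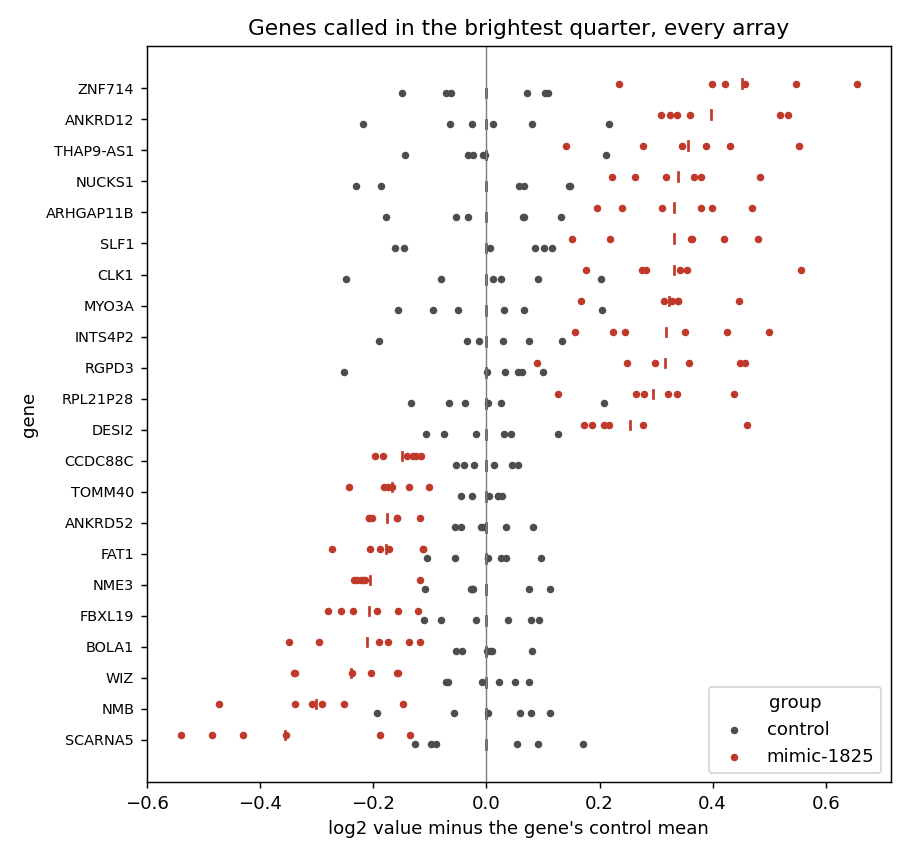
Each row is 1 of the 22 genes named from the brightest 25% of transcript clusters, and each point is 1 array, placed on the horizontal axis by its log2 value minus the gene's control mean (6 control and 6 mimic-1825 arrays, vertical ticks are group means). The 12 raised genes lie between log2 fold changes of 0.25 for DESI2 and 0.45 for ZNF714, and the 10 lowered genes between -0.15 for CCDC88C and -0.36 for SCARNA5.

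TBCB, which encodes tubulin folding cofactor B and was named in advance because the ALS study behind the series is known to have examined it, did not pass the threshold. Its mean log2 value was 9.18 ± 0.08 in controls and 9.11 ± 0.05 after the mimic (n = 6 each). The log2 fold change was -0.07 with a 95% interval from -0.18 to 0.03 (0.951-fold; limma adjusted p = 0.624), and 5 of 6 mimic arrays lay below the control mean. Without control replicate 2, the highest of the controls, the log2 fold change was -0.04. Of the 7 tubulin folding cofactor genes measured, 3 had higher and 4 lower means, and 0 passed with limma, over all clusters, adjusted over the list alone or at an unadjusted p under 0.05. TBCD had a log2 fold change of -0.09, TBCE of 0.11 and TBCEL of 0.07. The list as a whole had a median log2 fold change of -0.01 (camera adjusted p = 0.835). POFUT1, the gene within whose span miR-1825 lies, had a log2 fold change of -0.06 with an interval from -0.18 to 0.07 (limma adjusted p = 0.759). It does not measure the transfected mimic.

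G2/M genes, which act in the late cell cycle and mitosis, were the 1 list of 20 that passed the camera test, and it was higher after the mimic. Of 27 measured members, 21 had higher and 6 lower means, with a median log2 fold change of 0.07. The list score rose by 0.06 log2 units, or 4.36%, from 3.66 ± 0.02 to 3.72 ± 0.02 (n = 6 each), and all 6 mimic arrays lay above all 6 controls. The rise was uneven: mimic replicates 1, 2 and 3 scored 3.73, 3.75 and 3.73, and mimic replicates 4, 5 and 6 each scored 3.70. Controls did not follow that order, and the highest was control replicate 5 at 3.68. Every replicate number occurs in both groups, so a batch along the numbers and shared by both groups could not by itself make the difference. The list stayed past the camera threshold with a replicate block. Whether the size of the shift differed along the numbers was not tested. The camera adjusted p was 9.23e-05, and the list's call was lost with an estimated correlation (adjusted p = 0.218 with an estimated correlation). The exact permutation p of the score was 0.00216, the smallest that 924 assignments can give, or 0.0216 adjusted over the 20 lists. Over all clusters 0 members passed with limma, 9 had an unadjusted p under 0.05, all of them higher, and 1 passed adjusted over the list alone. That gene was CCNB1, the cyclin that activates CDK1 at entry into mitosis, which rose from 9.80 ± 0.05 to 10.01 ± 0.03 (1.15-fold, limma adjusted p = 0.00542, adjusted over the list alone). CCNB1 also passed in the brightest 25% of clusters (limma adjusted p = 0.0142), where the calls were unstable. CKAP2, a spindle protein gene, had a log2 fold change of 0.12, NUSAP1, a microtubule-binding spindle protein gene, of 0.10 and ECT2, which drives cytokinesis, of 0.12, each with a limma adjusted p of 0.0930, adjusted over the list alone. G1/S genes, which act at DNA replication, did not pass (camera adjusted p = 0.835), with 15 of 25 members higher and a median log2 fold change of 0.01. Their score difference of 0.01 turned to -0.01 after quantile normalization. Within that list CCNE2 had a log2 fold change of 0.17, CLSPN of 0.11, CDC6 of 0.10 and CDT1 of -0.12.

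**Figure D2:**
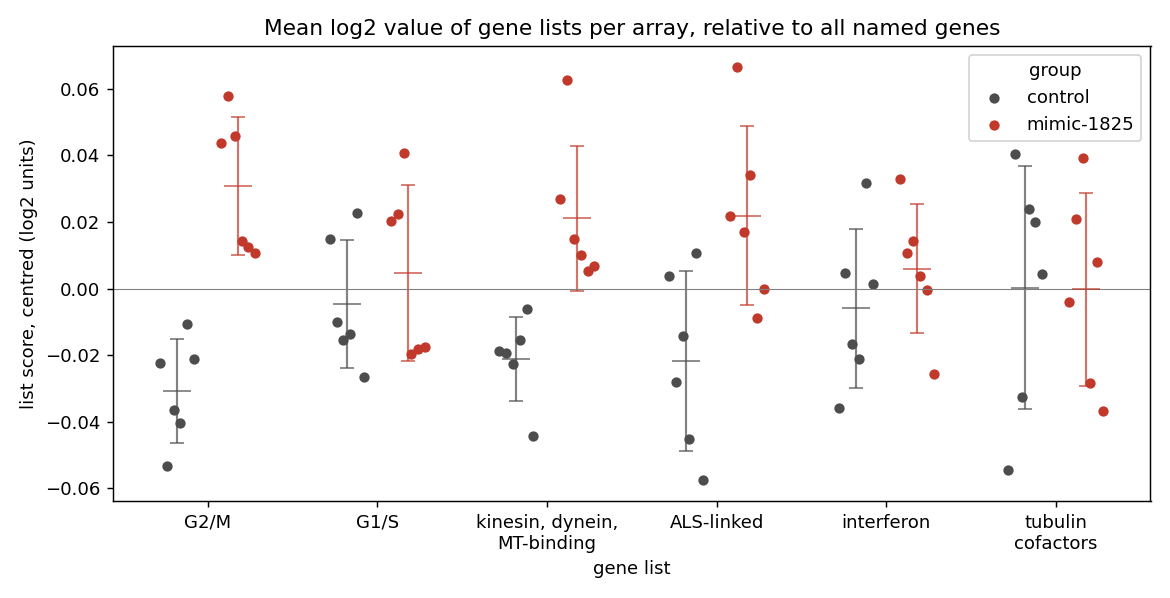
Points are the 12 arrays (control and mimic-1825, 6 each), placed vertically by their list score in log2 units (mean of the list's genes minus the mean of all 14884 genes, centred on 0 for each list), with bars for the mean and SD. For G2/M genes all 6 mimic arrays lie above all 6 controls, and the difference of means is 0.06; for tubulin folding cofactors the 2 groups overlap.

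**Figure D3:**
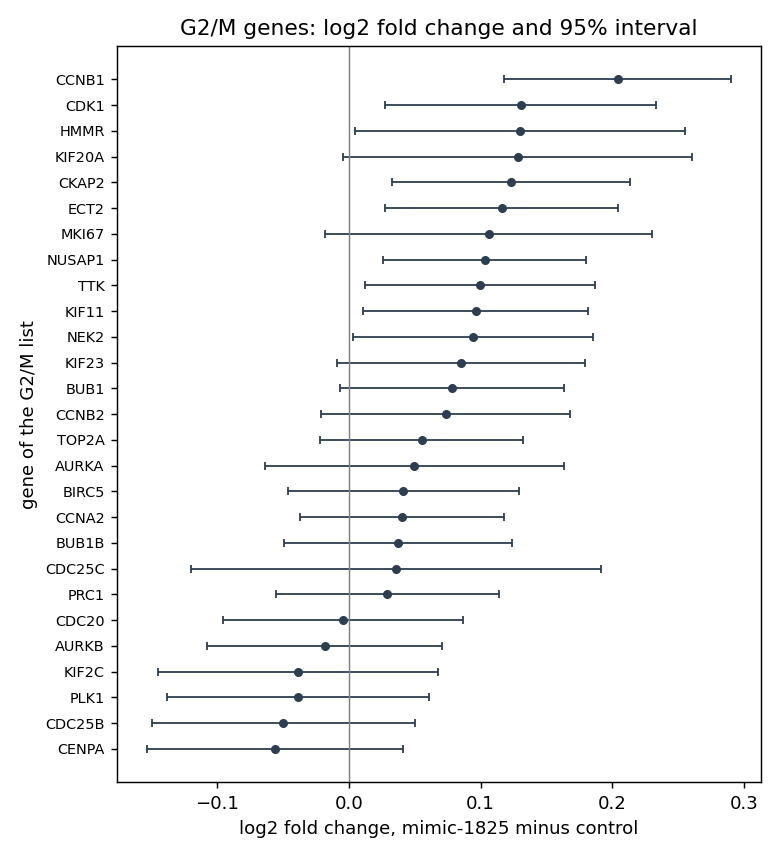
Each row is 1 of the 27 measured G2/M genes, with its log2 fold change (mimic-1825 minus control, horizontal axis) and its 95% limma interval. CCNB1 has the largest value, 0.20, and 21 of the 27 genes lie above 0.

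Kinesin, dynein and microtubule-binding genes had 20 of 27 members with higher means and a median log2 fold change of 0.04. The list did not pass camera (adjusted p = 0.251). Its score differed by 0.04, with all 6 mimic arrays above all 6 controls (exact permutation p = 0.00216, adjusted 0.0216). With limma 0 members passed over all clusters or adjusted over the list alone, and 3 had an unadjusted p under 0.05, of which 2 were higher. KIF3A, a kinesin-2 motor gene, had a log2 fold change of 0.24 (limma adjusted p = 0.0558, adjusted over the list alone), KIF3C of 0.16, KIF5B of 0.09 and CLASP1 of -0.13.

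ALS-linked genes had 18 of 28 members with higher means, a median log2 fold change of 0.04 and a camera adjusted p of 0.102. With limma 0 passed over all clusters, 7 had an unadjusted p under 0.05 (6 higher) and 3 rose when adjusted over the list alone. They were CHMP2B, a component of the ESCRT-III membrane-scission machinery (1.13-fold), HNRNPA1, an RNA-binding protein gene (1.15-fold), and TARDBP, which encodes the RNA-binding protein TDP-43 (1.17-fold), each with a limma adjusted p of 0.0443, adjusted over the list alone. CHMP2B also passed in the brightest 25% of clusters (limma adjusted p = 0.0401). HNRNPA2B1 had a log2 fold change of 0.12. HNRNPA1 and HNRNPA2B1 have processed pseudogenes with near-identical sequence. Mimic replicate 4 was the highest for TARDBP, at 9.17 against 8.78 to 8.91 in the other 5 mimic arrays.

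The interferon list, fixed because double-stranded RNA can set off this response, did not pass (camera adjusted p = 0.828), with 16 of 29 members higher, 13 lower and a median log2 fold change of 0.02. Both groups had been transfected with RNA, the mimic or the control siRNA, and no untransfected arrays were included. A response shared by both groups would therefore not show in this comparison. EIF2AK2, the double-stranded RNA-activated kinase PKR, had a log2 fold change of 0.16 (limma adjusted p = 0.0590, adjusted over the list alone) and passed in the brightest 25% of clusters (limma adjusted p = 0.0358). IFI44L had 0.18, IFIT5 had 0.12 and RSAD2 had -0.19, with RSAD2 and IFI44L near the low end of the scale at means under 5. The microRNA pathway list had 8 of 13 members higher and a camera adjusted p of 0.792. In that list the exonuclease gene XRN1 had a log2 fold change of 0.09 and the microprocessor subunit gene DGCR8 of 0.14.

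Stress and metabolic lists did not pass. Stress response genes had 7 of 17 members higher (camera adjusted p = 0.835). Of the 17, 1 fell when adjusted over the list alone: SDF2L1, an endoplasmic reticulum chaperone complex gene, with a log2 fold change of -0.29 (limma adjusted p = 0.0394, adjusted over the list alone). VLDLR had 0.19. Cholesterol synthesis genes had 8 of 17 higher, with a mean log2 fold change of 0.02 and a median of -0.003 (camera adjusted p = 0.792). STARD4, a sterol carrier gene, had 0.21 and HMGCS1, which encodes the synthase upstream of HMG-CoA reductase, had 0.14. Targets of p53 had 5 of 13 higher (camera adjusted p = 0.835), with BBC3, the apoptosis gene also called PUMA, at -0.19 and SESN1 at 0.11. Heat shock genes had 9 of 12 higher and a camera adjusted p of 0.724, with CHORDC1 at 0.17. Oxidative phosphorylation genes had 9 of 15 higher, with UQCRB at 0.27, and ribosomal protein genes had 24 of 43 higher, with RPL31 at 0.27. Both UQCRB and RPL31 have processed pseudogenes, and the camera adjusted p of the lists was 0.835 and 0.792. Hypoxia genes had 7 of 17 higher, with HK2 at -0.11. Their median of -0.01 and the camera direction were negative while the mean, 0.0005, was above 0 (camera adjusted p = 0.857). Lysosome and autophagy genes had 11 of 26 higher, with LAMP2 at 0.11, a median of -0.01 and a mean of 0.003 (camera adjusted p = 0.991).

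Lists for sample handling and for other cell types did not pass either. Immediate early genes had 12 of 23 higher, a mean of -0.01 and a median of 0.002 (camera adjusted p = 0.835), with IER2 at -0.21. Housekeeping genes had 4 of 6 higher and a median of 0.01 (camera adjusted p = 0.835). Fibroblast markers had 2 of 5 higher, leukocyte markers 1 of 7 and markers of epithelial cancer lines 3 of 11, with median log2 fold changes of -0.05, -0.08 and -0.02 and camera adjusted p values of 0.792, 0.724 and 0.792. CLDN7, a tight junction gene of the epithelial list, had -0.22. The G2/M difference stood beside negative means in all 3 lists of other cell types, none of them past the test. The score differences of hypoxia, lysosome and housekeeping genes, 0.0008, 0.003 and 0.01 as deposited, were each -0.01 after quantile normalization.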

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

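In 164 groups of 6 arrays (62 genes and 20 list scores, each in both treatment groups), the highest or lowest array was tested for a gap to the rest, and 11 stood apart where chance gives about 1 in 20. For TBCB, control replicate 2 was the highest control at 9.33, against 9.09 to 9.18 in the other 5. For RSAD2, control replicate 4 was the lowest at 3.77, against 4.06 to 4.13. For RGPD3, control replicate 6 was the lowest at 7.54, against 7.80 to 7.90. The p53 list score of control replicate 6 was 1.55, against 1.62 to 1.65, and the leukocyte list score of control replicate 1 was -1.63, against -1.47 to -1.41. Among mimic arrays, TARDBP was highest in replicate 4 at 9.17, against 8.78 to 8.91. IFI44L and SESN1 were highest in replicate 3, at 4.98 (others 4.56 to 4.67) and 9.21 (others 9.07 to 9.10). DESI2 was highest in replicate 4 at 9.49, against 9.20 to 9.31. NME3 was highest in replicate 2 at 8.04, against 7.92 to 7.94. The kinesin, dynein and microtubule-binding score was highest in mimic replicate 2, at 1.37 against 1.32 to 1.34.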

How the results depend on the processing

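The fits of the brightest 25% of clusters under a second changed setting, and those without both arrays numbered 2, were chosen after seeing the data. The count of 6 calls became 0 with a replicate block, with 1 cluster per named gene, at an adjusted p of 0.01 and without both arrays numbered 2, and 1 with a fold minimum of 1.5. It was 13 at or above the median mean value, 242 in the brightest 25% and 39 with a trend and robust prior, and it ranged from 0 to 6 without single arrays. The largest unadjusted p called rose from 4.18e-06 over all clusters to 8.76e-04 in the brightest 25%, where 21.4% of clusters had an unadjusted p under 0.05. The count of 242 in the brightest 25% became 9 with a replicate block (2806 at an unadjusted p under 0.05, against 2863), 144 with centred arrays, 448 with a trend and robust prior, 550 in the brightest 10%, 24 in the brightest 40%, 2 without both arrays numbered 2, and 23 to 262 without single arrays. It was 239 with quantile normalization (126 higher, 113 lower), which shared 173 calls. Of the 22 genes named from the 242, 1 was called with the block and 0 without both arrays numbered 2. The numbers did not pair the samples (0 control arrays correlated best with their own number), so calls lost with the block do not show a weaker effect. The G2/M list shift of 0.06 kept its direction in all 23 alternatives, between 0.04 and 0.07, and was past the threshold in 22. The replicate block, centring, the trend and robust prior, the estimated correlation and fry could not change this shift, which is taken relative to all named genes. Apart from fry and the estimated correlation, these alternatives kept the preset correlation of 0.01. With an estimated inter-gene correlation the shift stayed 0.062 but 0 of the 20 lists passed. Camera otherwise called 1 list in every alternative run, and so did the directional test of fry. The mixed test of fry, which asks whether members change in either direction, called 9 of the 20. The replicate block, the trend and robust prior, the filters and the use of 1 cluster per gene leave a gene's log2 fold change as it is. These settings could not turn the direction of a gene. TBCB stayed negative and uncalled in 21 alternatives (-0.09 to -0.04, adjusted p 0.321 to 0.827). The 61 other named genes kept their direction in all 1272 values, and 28 of these values crossed the threshold. The causes were not tested. Planned settings on seed sites and TUBA4A were not run.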

Other observations

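The tests of the array composition axis, of both axes on the second mitosis list, of the G2/M minus G1/S score and of the microRNA rows were chosen only after the result was seen, and the second mitosis list, the gene classes and the tests of the brightest 25% of clusters after the data were first examined. A second list of mitosis genes, outside the fixed G2/M list, was also higher after the mimic. In this list of 50 measured genes, written without the mitosis genes that had already been seen among the smallest p values, 43 had higher and 7 lower means. Its score rose by 0.07 log2 units, from 2.32 ± 0.03 to 2.39 ± 0.03 (n = 6 each, exact permutation p = 0.00649, adjusted 0.0260 over 8 such sets), and 4 of 6 mimic arrays lay above all controls. After quantile normalization the difference was 0.05, with 6 of 6 above (exact permutation p = 0.00216). Camera gave p = 3.76e-08, and p = 0.0406 with an estimated correlation. With an array composition axis (zinc finger minus pre-microRNA means) as a covariate the difference went from 0.070 to 0.016 (95% interval -0.012 to 0.045), and with the principal axis of within-group variation to 0.055 (0.037 to 0.072). The score followed the composition axis within groups (Pearson r = 0.897 over 12 arrays, permutation p = 0.00107, adjusted 0.00321 over 3 relations; Spearman rho = 0.909, permutation p = 4.6e-04, adjusted 0.00138; r = 0.884 without the 2 arrays farthest from the median of the axis). That axis may therefore carry most of the difference of this list, which is not separate evidence for the G2/M shift. Adjusted over the list alone, 2 genes rose, both of the chromosome attachment machinery: KIF18A, a kinesin that dampens chromosome movements, and KNL1, a kinetochore scaffold gene, each with a limma adjusted p of 0.0469, adjusted over the list alone, and log2 fold changes of 0.20.

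The 509 zinc finger genes (symbols starting with ZNF or ZFP) scored 0.04 higher after the mimic (exact permutation p = 0.0130, adjusted 0.0260), and also 0.04 after quantile normalization (exact permutation p = 0.0173). The 1072 microRNA genes, measured through probes for their precursors, differed by -0.04 (exact permutation p = 0.0216, adjusted 0.0346), and after quantile normalization by -0.02 (exact permutation p = 0.110). The 1398 long non-coding RNA genes differed by -0.02 (exact permutation p = 0.0671, adjusted 0.0767), and after quantile normalization by -0.00075 (exact permutation p = 0.755).

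The G2/M shift was set against other accounts. In 100 splits of the 12 arrays into 6 and 6, only the real one, 1 of 100, gave a camera p as small (4.61e-06, against 1.63e-05 in the closest other split). The list had been picked as the 1 of 20 that passed camera on these same arrays. The other splits were not searched for their own best list, so they do not exclude chance for a list picked in this way. Expression level and genomic span were weighed through matched random lists, which cannot settle their part for a list picked on these arrays. The list's median of 0.07 stood at percentile 99.94 of 10000 random lists matched on both. The middle 95% of those lists ran from -0.010 to 0.053, so level and span may carry part of it. Random lists also lack the correlation between G2/M genes, so the percentile may overstate how unusual the list is. With the composition axis as a covariate the difference went from 0.062 to 0.040 (95% interval 0.013 to 0.068). That axis, formed from zinc finger and pre-microRNA means after the result was seen, measures array composition only roughly. The difference left beside it therefore does not settle how much the axis carries. It may carry part or all of the shift, since the G2/M score followed it within groups (Pearson r = 0.635 over 12 arrays, permutation p = 0.0275, adjusted 0.0413). Spearman rho was 0.692 (permutation p = 0.0220, adjusted 0.0330), and r was 0.902 without the 2 arrays farthest from the median of the axis. With the principal axis of within-group variation the difference went to 0.055 (0.037 to 0.072). That axis did not differ clearly between the groups (exact permutation p = 0.398), so it could take away little and no conclusion is drawn from it. The G2/M minus G1/S score was higher by 0.05 after the mimic (exact permutation p = 0.00433, adjusted 0.0260). Of the 6 mimic arrays, 5 lay above all controls. The G1/S score itself differed by 0.01 (exact permutation p = 0.494), and by -0.01 after quantile normalization. These values argue against a like rise of both lists, as a larger share of cells cycling at all phases would give. The G1/S members went both ways, with an SD of 0.066 between members, and their median lay below that of G2/M by 0.061. The G2/M list had been picked on these same arrays, so a smaller part for the share of cycling cells stays open. Also open are effects of the mimic on the mitotic phase and of the control siRNA. A batch that no label gives and transcript GC content, for which no sequences were used, stay open as well.

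The calls were set against chance and against the spread within groups. None of the 99 other splits gave as many calls as the real one (1 of 100): the highest other was 2 against 6 over all clusters, 1 against 242 in the brightest 25% of clusters, and 4683 against 5770 at an unadjusted p under 0.05. The brightest 25% was singled out among the filters after the data were seen. The other splits were not searched for their own best filter, so they do not exclude chance for the 242. With the principal axis of within-group variation as a covariate, the median size of the 242 changes stayed at 95.4% of its value (93.2% to 99.3% without single arrays), and 126 of the 242 still passed among 153 calls. That axis did not differ clearly between the groups (exact permutation p = 0.398). As a covariate it could take away little of a group difference, so no conclusion is drawn from it. The 242 followed the axis within groups about as closely as the other 13163 clusters did (median size of r 0.340 against 0.329). The composition axis, which did differ between the groups (exact permutation p = 0.0130), was not fitted to the 242 and stays open as a cause. The balance of higher and lower calls moved with the scaling (191 higher and 51 lower as deposited, 126 and 113 after quantile normalization), and transcript GC content, a batch and the treatment itself remain open.

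The lower pre-microRNA rows may be part of an array composition axis that also runs within the groups, as a hypothesis. Within groups, arrays with higher zinc finger means had lower pre-microRNA means (Pearson r = -0.612 over 12 arrays, permutation p = 0.0488, adjusted 0.0488; Spearman rho = -0.650, permutation p = 0.0398, adjusted 0.0398; r = -0.654 without the 2 farthest arrays). Whether the shift belongs to rows near background stays open: the 339 brighter rows differed by -0.05, with an exact permutation p of 0.301. No biological explanation was tested for this pattern.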
